A study of Mus musculus with 768 samples.

How the data were processed

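RNA was measured in 768 single cells sorted from the thymus of C57BL/6 mice aged 6 to 8 weeks, on 8 plates of 96 cells. Per the labels, the mice were of 4 genotypes: wild type (WT), germline Tcf7-/-, Tcf7fl/fl with Vav-cre, a recombinase active in all blood cells, and Tcf7fl/fl with Lck-cre, a recombinase that becomes active in T-cell precursors. Tcf7 encodes TCF1, a transcription factor of early T-cell development. The cells came from 2 sort gates of CD4- and CD8-negative (DN) thymocytes without lineage markers. The DN1 gate took CD25-negative, CD44-positive cells, and the DN2-3 gate took CD25-positive cells. WT, Tcf7-/- and Vav-cre gave 1 plate per gate, and Lck-cre gave 2 plates of the DN2-3 gate.

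Per the submitters' processing notes, single-cell libraries were made with a modified STRT protocol and sequenced, reads were aligned with TopHat2 2.1.1 and counted with HTSeq, and the genome was mm10, also given as GRCm38 for 576 of the cells. The Tcf7-/- entries list mm10 alone and carry other labels than the rest, so these plates may form a batch of their own, and genotype and batch cannot be told apart for them. The notes do not say whether molecular identifiers were collapsed, and the labels name no sex and no animal. The authors deposited raw counts per gene and cell, in whole numbers with no normalization. The authors also deposited log2 values, log2(TPM/10 + 1). Within each cell these log2 values were proportional to the counts once turned back, to within 0.157%, so TPM there holds scaled counts without a gene length term. The genes of the count file held 88.6% of the total behind the authors' values in the median cell.

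The count file has 23154 entries. In 27 of them a date stood in place of the gene symbol, with 0.141% of the counts, and these were dropped, which left 23127 genes. No mitochondrial and no spike-in genes are in the file, so the planned limit of 20% mitochondrial counts removed nothing. Cells with at least 1000 detected genes were kept, 675 of 768. Counts were summed over the kept cells of each library and scaled by the summed total of the library, in CPM. Log2 ratios between libraries used a pseudocount of 10 CPM. For Lck-cre the value is the mean of the log2 ratios of both plates. No doublet caller was run, since cells were sorted singly into plates. Gene positions are those of the GENCODE annotation of mm10.

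Every gate and genotype except Lck-cre DN2-3 is 1 library, and no animals are named, so cells were not used as replicates of a genotype: no test between genotypes, p-value or count of changed genes is given. Intervals are 95% and, except where cells were resampled, exact: Poisson for a summed count, conditional binomial for a ratio of 2 summed counts, and Clopper-Pearson for a share of cells. They cover counting error only, and molecules amplified by PCR are not independent. Where a library had 0 counts of a gene, the ratio is a lower bound taken at a floor of 3 counts per library. The 2 Lck-cre plates are the only libraries of the same genotype and gate, and the difference between them is the yardstick for the other comparisons. The labels do not say whether these plates come from different animals, so the yardstick may hold no spread between mice. The DN1 gate has no such pair, and its libraries differ from these plates in cell types and depth. A library was compared with the WT library of its gate, WT DN2-3 with WT DN1, Vav-cre DN1 with Tcf7-/- DN1, and Lck-cre with Vav-cre DN2-3.

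The 20 gene lists, the cell type markers, the rule for named genes and the other choices of method were set before the data were examined. A list's members counted as measured at 10 CPM or more in a library of the comparison. Each list has the median log2 ratio of its measured members, the number at least 2-fold higher or lower, and the percentile of the median among 10000 random lists of the same size matched on expression in 20 bins. A list is said to stand apart when its percentile was under 2.5 or over 97.5, which describes these libraries and is no test between genotypes. Named genes had at least 50 CPM in a library and a count in at least 20% of the kept cells of the higher library, and the 10 with the highest and the 10 with the lowest log2 ratio were taken, for Lck-cre with the same sign on both plates. Unnamed gene models and Xist and Y-linked genes were left out of the naming. A gene that met the rule in the Lck-cre comparison is not reported here. T-cell receptor constant genes such as Trbc1, Trbc2, Trac and Trdc, and Ighm and Igkc, are absent from the file and are not analysed here.

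Cells were clustered together with scanpy 1.11.5 on log-normalised counts, with 2000 variable genes, 15 components, 15 neighbours and Leiden resolution 1. Tcf7, the S phase and G2 and M phase lists, Xist and Y-linked genes were kept out of the clustering. A cluster took the name of the class, among 11 with fixed markers, with the most raised markers (at least 2 counts in at least 20% of its cells and a CPM at least 2-fold above the rest). It needed 3 or more raised markers and more than the next class. It stayed unnamed where its 10 leading genes held more markers of another class, or where its cells were shallow for their library, a limit set after the clusters were seen.

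The other choices set at that point were all cells, cells with at least 2000 genes, cells weighted equally, a pseudocount of 1 CPM, edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, the mean of the deposited log2 values, cells thinned to 8908 counts, cells without markers of other blood cell types, list minimums of 0 and 50 CPM, each Lck-cre plate alone, Leiden resolutions of 0.5 and 2, and 1000 variable genes. Added after the data were seen were the totals behind the authors' values, counts of 1 to 5 set to 0, each gene without its highest cell, NK-like cells alone, with and without counts of 1 to 5, and cluster names without the limit on depth. Cells were left out as carrying markers of other blood cell types when they had counts of at least 3 markers of 1 class. A single count of a marker was enough. The choice left 9 of the 86 WT DN1 cells, although 72 of the 86 were NK-like. Being left out therefore does not show that a cell was of another type. The classes were B-like, myeloid-like, dendritic-like, erythroid-like and mast or basophil-like. Many of these markers are also members of the dendritic, myeloid and erythroid and mast lists, so a fall of these lists follows partly from the choice itself. A gene under 10 CPM in both libraries once cells are left out by type has no value there. The steps were tested on simulated data built from the WT counts: of 50 genes raised 4-fold and 50 lowered to 0.25 of their level, 100% came out at least 2-fold changed in the simulations of both Vav-cre DN1 and Tcf7-/- DN2-3, and of the unchanged genes 0%. Genes changed exactly 2-fold passed that limit in 10% to 36%. The simulated library sums were Poisson draws, read for genes at 50 CPM or more, without variation between cells or from PCR. These shares test the calculation and do not give the rate of false changes in the real libraries. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3.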

Results

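Single-cell RNA counts were collected from thymocytes of 2 sort gates in WT mice and in mice labelled as having Tcf7 deleted in the germline, by Vav-cre or by Lck-cre, to follow the role of TCF1 at successive stages. The DN1 libraries kept 86 WT, 96 Tcf7-/- and 58 Vav-cre cells of 96 each, with summed totals of 7112702, 4159404 and 1547512 counts. The DN2-3 libraries kept 88 WT, 93 Tcf7-/- and 76 Vav-cre cells and 91 and 87 Lck-cre cells, with totals of 4976245, 8371808, 4381685, 6112207 and 5841167. The median kept cell held 66572 counts in WT DN1, 37088.5 in Tcf7-/- DN1 and 19293 in Vav-cre DN1, and between 43592.5 and 70003 in the DN2-3 libraries. The smallest libraries give the widest intervals: for 0 counts the upper limit is 2.38 CPM in Vav-cre DN1 and 0.519 CPM in WT DN1, and the floor of 3 counts used for ratios is 1.94 and 0.422 CPM. Only Lck-cre DN2-3 has 2 plates, which are not named as different animals. Between the 2 Lck-cre plates the median absolute log2 ratio of the 3712 genes at 50 CPM or more was 0.25, and for 5% of genes it was above 0.85.

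Tcf7 itself (chromosome 11, 52252371 to 52283014, minus strand, mm10) was far lower in the Tcf7-/- DN2-3 library, at 122 CPM (interval 115 to 130.0), than in WT DN2-3, at 862 CPM (836 to 888), a log2 ratio of -2.72. In the DN1 gate the Tcf7-/- library had 98.6 CPM (89.3 to 109) and WT had 134 CPM (125 to 143), a log2 ratio of -0.41 that was 0.56 with cells weighted equally and 0.28 with thinned cells. The libraries labelled Vav-cre did not show lower Tcf7: 368 CPM (339 to 400.0) in DN1, a log2 ratio of 1.40 against WT DN1, and 964 CPM (936 to 994) in DN2-3, a log2 ratio of 0.16. The libraries labelled Lck-cre had 762 and 658 CPM, a mean log2 ratio of -0.28 (-0.18 and -0.38 by plate). Tcf7 counts were found in 97.7% of WT, 71% of Tcf7-/- and 100% of Vav-cre DN2-3 cells, and in 96.7% and 96.6% of the Lck-cre cells. In the DN1 gate they were found in 57% of WT, 84.4% of Tcf7-/- and 60.3% of Vav-cre cells, at a median of 1, 2 and 2 counts per cell, and with counts of 1 to 5 set to 0 in 32.6%, 20.8% and 37.9%. The files give neither the deleted exons nor the part of the transcript that was counted, so transcripts that lack the deleted part could still be counted, and a library whose label is wrong would look alike. Tcf7 counts therefore do not show whether TCF1 was lost, and each Vav-cre and Lck-cre value below is that of a library under its label. Lef1, the related factor of the same family, was highest in Tcf7-/- DN2-3 at 921 CPM, against 347 CPM in WT, 548 CPM in Vav-cre and 273 and 324 CPM in the Lck-cre plates.

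**Figure D1:**
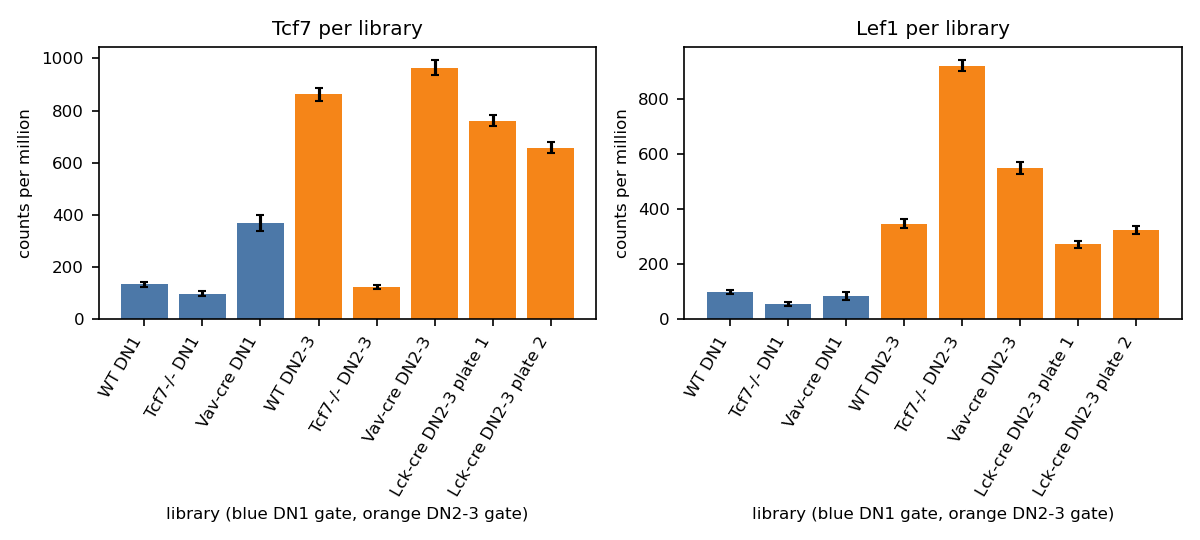
CPM of Tcf7 and Lef1 in each of the 8 libraries, with 95% Poisson intervals as error bars and the gate as the colour. Among DN2-3 libraries, the Tcf7-/- library is the lowest for Tcf7, at 122 CPM, and the highest for Lef1, at 921 CPM.

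The WT libraries of both gates differ in cell type as well as in stage: 72 of the 86 WT DN1 cells (83.7%) fell in an NK-like (natural killer) cluster and 1 in an early progenitor-like cluster, so this comparison sets mostly NK-like cells against DN2-3 thymocytes. The name rests on raised markers alone. No class covered mature alpha-beta T cells, with or without NK receptors, and T-cell receptor constant genes are absent from the file. Such cells could therefore carry this name, and WT DN1 also held the T-cell genes Cd28 and Cd5 (below). Of 18 measured DN3 and DP stage genes, 9 were at least 2-fold higher in WT DN2-3 and 3 lower. Among the higher, Dntt, which adds nucleotides at T-cell receptor joints, had 3037 against 13.5 CPM, Rag1, part of the recombinase, 223 against 6.05 CPM, and Ptcra, the invariant pre-T-cell receptor chain, 147 against 1.12 CPM. Genes of NK and innate lymphoid cells (ILC) were far higher in the WT DN1 library: Cd7 had 1269 against 0.603 CPM, the inhibitory receptor gene Klra9 1348 against 1.41 CPM, the chemokine gene Ccl5 1004 against 3.82 CPM, and Id2, a factor that ILCs depend on, 3013 against 75 CPM. The genes that define the gates went with the sort: Il2ra (CD25) had a log2 ratio of 3.80 and Cd44 of -3.98. Tcf7 had a log2 ratio of 2.60 and Lef1 of 1.71. Cd2, an adhesion receptor of T and NK cells, had 448 CPM in WT DN1 and 0 counts in WT DN2-3, at least 743-fold lower.

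By list, 19 of 21 measured NK and cytotoxic genes were at least 2-fold lower in WT DN2-3 (median -4.49, or -5.12 with genes at 0 set to their bound), and 12 of 19 ILC genes (median -2.15, or -2.36), with Icos at -5.35 and Cxcr6 at -5.31. Of 25 T-lineage genes, 11 were higher and 6 lower by 2-fold (median 0.60). The Notch target list had a median of 2.35 (2.79 with the bound), with Hes1 at 4.03, the DN3 and DP stage list 0.92, the S phase list 1.05, the G2 and M phase list 1.98 (2.26) with Top2a at 3.25, the Myc and ribosome biogenesis list 0.64, and the Wnt and TCF1-linked list 1.16. The thymic stroma list had 3 measured genes and a median of 2.13. Medians were -1.27 for early progenitor, -1.25 for gamma-delta T, -1.31 (-2.08) for B cell, -2.26 (-2.67) for dendritic and -0.54 for dissociation stress genes, and all of these lists stood apart from random lists. The myeloid (-0.64, or -2.23 with the bound), erythroid and mast (0.25), T-cell leukaemia factor (0.28), p53 and apoptosis (-0.07) and sort and housekeeping (-0.41) lists did not. The 10 genes named highest were Dntt, Arpp21, Endou, Ly6d, Cdk6, Cpa3, Aqp11, Dgkeos, Rgcc and Myb, and the 10 lowest Cd7, Klra9, Ly6c2, Cd52, Ccl5, S100a6, Klrd1, Gimap4, Klrk1 and H2-Eb1. A single WT DN1 cell held 57.8% of the H2-Eb1 counts, and without the highest cell of each gene the dendritic median was -1.04 and the early progenitor median -0.51. Without cells carrying markers of other blood cell types, which leaves 9 WT DN1 cells, the early progenitor median was 0.63. This choice drops most NK-like WT DN1 cells, so it does not single out cells of other types.

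The DN1 libraries labelled Tcf7-/- and WT differ in makeup: with 1 early progenitor-like cell of 86, WT DN1 holds few of the earliest thymic cells, and the values here set a library of 24% NK-like, 31.3% ILC-like and 17.7% early progenitor-like cells against one of mostly NK-like cells. The Tcf7-/- DN1 library had more transcripts of early progenitors: Cd34, a stem and progenitor surface marker, had 126 CPM against 0 counts in WT (at least 299-fold higher), Mpo, the granule peroxidase of myeloid precursors, 135 CPM against 0 counts (at least 320-fold), and Lyl1, a progenitor transcription factor, a log2 ratio of 3.11. Cpa3, the protease of mast cells and early progenitors, had 415 against 1.41 CPM. Of the Ly49 family of NK receptors, Klra9 had 27.9 against 1348 CPM and Klra3 1.44 against 227 CPM, while the wider NK and cytotoxic list went both ways. The T-cell costimulatory receptor gene Cd28 had 27.9 against 404 CPM, and Cd5, a regulator of T-cell receptor signals, 24.8 against 192 CPM.

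Of 16 measured early progenitor genes in this comparison, 10 were at least 2-fold higher and 0 lower (median 1.60), and of 22 ILC genes 10 were higher and 0 lower (median 0.76), with Rora at 2.02 and Lta at 3.21, though 1 cell held 67.7% of the Lta counts. Of 24 T-lineage genes, 3 were higher and 7 lower (median -0.68), and the median was -0.38 with cells weighted equally, -0.27 with thinned cells, -0.26 without cells carrying markers of other blood cell types and -0.085 on the deposited log2 values. The NK and cytotoxic list, with 5 higher and 5 lower of 22, had a median of -0.43, with Tbx21, the factor that directs NK maturation, at -1.61. Medians were 1.126 for gamma-delta T genes, with the scavenger receptor gene Cd163l1 at 3.01, 0.70 for T-cell leukaemia factors, 0.81 for Notch targets, 0.63 for DN3 and DP stage genes, 0.70 for myeloid and 1.04 for erythroid and mast genes, and each stood apart from random lists. Of 23 G2 and M phase genes 19 were higher (median 1.63, or 1.77 with the bound), but 1 cell held 90.9% of the Ube2c and 94.3% of the Ccnb1 counts, and without the highest cell of each gene the median was 0.52. The named genes were Cpa3, Ccl1, Scin, Ube2c, Deptor, Ifitm2, Mpo, Cd34, Chad and Car2 among the higher, and Klra9, Klra3, Klra13-ps, Cd28, Naaa, Klra7, Sidt1, Cd5, Klra6 and Styk1 among the lower. One cell also held 98% of the Ccl1 counts and 72.5% of the WT Naaa counts. Genes of the DN2-3 gate were found at low counts throughout this library: Il2ra in 72.9% of cells at a median of 1 count, Ptcra in 72.9% and Dntt in 96.9%. With counts of 1 to 5 set to 0, the DN3 and DP stage median was -0.22.

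Vav-cre, active in blood cells from the stem cell on, addresses the same gate by another route, and the comparison rests on the same mostly NK-like WT library. In the library labelled Vav-cre DN1, ILC and progenitor genes were also higher: Rora, a factor of ILCs, had 306 against 29.1 CPM, and Kit, the stem cell factor receptor, 130 against 10.1 CPM. Of the Ly49 family, Klra9 had 0 counts against 1348 CPM (at least 695-fold lower), Klra13-ps 0 counts against 218 CPM (at least 112-fold) and Klra1 18.1 against 370.2 CPM. Cd28 had 14.2 against 404 CPM, Cd5 8.40 against 192 CPM, and Id3, an inhibitor of E proteins, a log2 ratio of -3.39. Il2ra was higher, 169 against 9.70 CPM.

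In this library 15 of 18 measured early progenitor genes were at least 2-fold higher (median 1.53, or 1.63 with the bound), 13 of 22 ILC genes (median 1.32) with Cxcr5 at 2.31, and 14 of 15 myeloid genes (median 1.65, or 2.05), with S100a8 at 3.10. Of 21 T-lineage genes, 1 was higher and 9 lower (median -0.65), with Sh2d1a at -3.03. Medians were 1.68 for gamma-delta T, 0.80 for dendritic and 1.12 for T-cell leukaemia factor genes and -0.39 for the NK and cytotoxic list, where 7 genes were higher and 10 lower of 23. The G2 and M phase median was 0.19 over 8 measured genes, which did not stand apart. The named genes were Cd209d, Chad, Upp1, Bicd1, Hacd4, Serpina3g, Batf3, Cd63, Car2 and Tns4 among the higher, and Klra9, Styk1, Klra13-ps, Klra7, Cd28, Klra1, Cd40lg, Cxcr3, Cd5 and Aif1 among the lower. Single cells held 97.6% of the Cd209d, 78.4% of the Cd63, 92.9% of the Csf1r and 63.3% of the Meis1 counts here and 88.2% of the Aif1 counts in WT, and without the highest cell of each gene the myeloid median was 1.03. Chad and Car2 were named among the higher genes, and Cd28, Cd5, Klra13-ps, Klra7, Klra9 and Styk1 among the lower, in both DN1 comparisons, which share the WT library. This library is the smallest, and with cells of at least 2000 genes, 24 of the 58, the ILC median was 0.62 and the Tcf7 log2 ratio 0.61.

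**Figure D2:**
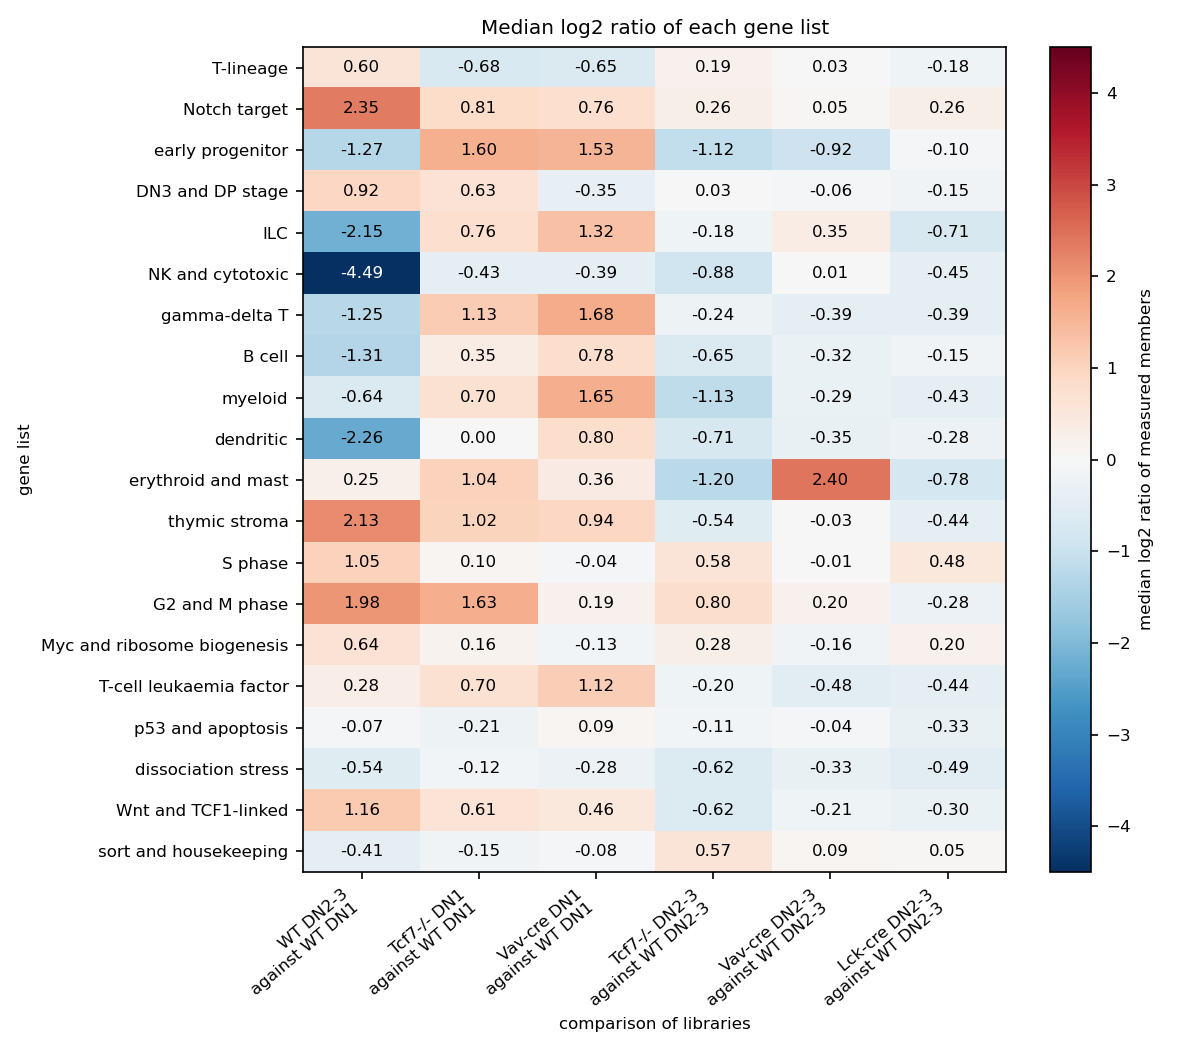
Median log2 ratio of the measured members of each of the 20 gene lists (vertical) in the 6 comparisons with WT (horizontal), with the value in each cell and colour from blue (lower) to red (higher). The early progenitor list is at 1.60 and 1.53 in the Tcf7-/- and Vav-cre DN1 comparisons and at -1.12 and -0.92 in the DN2-3 comparisons.

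The cell types behind the DN1 libraries differed. Cells in the NK-like cluster made up 83.7% of WT DN1 (72 of 86, interval 74.2% to 90.8%), 24% of Tcf7-/- DN1 (15.8% to 33.7%) and 15.5% of Vav-cre DN1 (7.35% to 27.4%). ILC-like cells made up 8.14% (3.34% to 16.1%), 31.3% (22.2% to 41.5%) and 67.2% (53.7% to 79%). Early progenitor-like cells were 1 of 86 in WT, 17 of 96 (17.7%) in Tcf7-/- and 5 of 58 (8.62%) in Vav-cre DN1. Another 24 of the 96 Tcf7-/- cells, and 4 of the 86 WT cells, fell in a cluster of shallow cells in which the NK markers Klrb1c, Klrd1 and Gzmb were raised and which was left unnamed for its depth; named by its markers alone it brings the NK-like share to 49% of Tcf7-/- DN1 (47 of 96) and 88.4% of WT DN1 (76 of 86). Within NK-like cells alone, 23 Tcf7-/- against 72 WT, Klra9 had a log2 ratio of -5.05, Cd28 of -2.18, Cd5 of -1.33 and Styk1 of -1.17, and the T-lineage median was 0.09 and the NK and cytotoxic median 0.54. Within the 9 Vav-cre NK-like cells Cd28 had a log2 ratio of -2.17, Styk1 of -4.85 on 1 count, the T-lineage median was -0.64 and the NK and cytotoxic median 0.36. At Leiden resolution 2 the ILC-like share was 6.25% in Tcf7-/- and 1.72% in Vav-cre DN1, because most of these cells fell in clusters without a name, and at resolution 0.5 the early progenitor-like share was 42.7% in Tcf7-/- DN1. The early progenitor-like cluster then held 52 cells at a median of 17076 counts, against 23 cells at 62337 at resolution 1, so shallower cells joined it. Whether the shallow cells described above are NK-like or progenitor-like is therefore not settled.

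**Figure D3:**
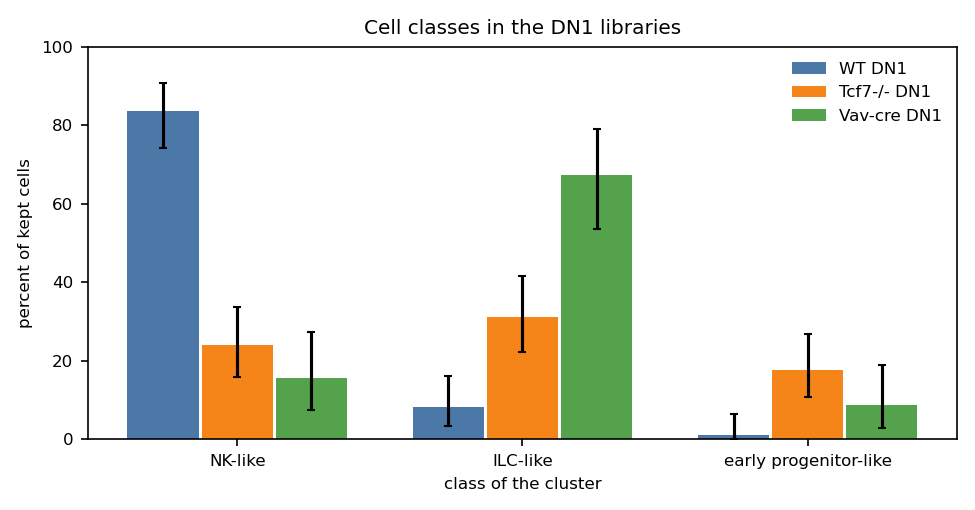
Percent of kept cells (vertical) in NK-like, ILC-like and early progenitor-like clusters (horizontal) in the 3 DN1 libraries, shown by colour, with exact 95% intervals. NK-like cells fill 83.7% of WT, 24% of Tcf7-/- and 15.5% of Vav-cre DN1.

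Compared directly, the Vav-cre DN1 library held more dendritic and myeloid transcripts than Tcf7-/- DN1 and fewer of Ptcra and Dntt. Cd74, the invariant chain of antigen presentation, had 1051 against 130.0 CPM and Siglech, a marker of plasmacytoid dendritic cells, 71.7 against 0.240 CPM, with 66.7% of its counts in 1 cell. Ptcra had 2.58 against 51 CPM and Dntt 30.4 against 217 CPM, with log2 ratios of -1.57 and -2.34 once counts of 1 to 5 are set to 0. Of 17 dendritic genes 10 were at least 2-fold higher (median 1.75), and of 15 myeloid genes 9 (median 1.12), while of 18 DN3 and DP stage genes 9 were lower (median -0.89, or -0.94 with the bound, and -0.36 with counts of 1 to 5 set to 0). The T-lineage median was -0.39, the ILC median 0.27, which did not stand apart, and the G2 and M phase median -1.71 (-1.85). Named genes were Cd209d, Cacnb3, Ifi30, Txndc16, Cd74, S100a8, Ccr7, Rapsn, Foxj2 and Ccdc88a among the higher and Ccl1, Ube2c, Ccnb2, Churc1, Cenpf, Cd24a, Cpa3, Nme4, Zbp1 and Osbpl1a among the lower. Single cells held 91% of the Cacnb3, 77.1% of the Ifi30 and 90.6% of the Ccr7 counts, and without the highest cell of each gene, Ccr7 went from 2.81 to -0.12, Cenpf from -3.30 to -0.77 and the G2 and M phase median to -0.40. Without cells carrying markers of other blood cell types the dendritic median was -0.32 and the myeloid median -0.13. Genes of these lists set which cells were left out, so this fall does not show which cells carried the transcripts.

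In the DN2-3 gate, germline loss of Tcf7 asks how cells committed to the T lineage differ without TCF1. The Tcf7-/- DN2-3 library held genes that had 0 counts in WT DN2-3: Pdlim4, a cytoskeletal adaptor, at 226 CPM (at least 376-fold higher), Cd2 at 205 CPM (at least 340-fold), the receptor gene Gpr83 at 91.4 CPM (at least 152-fold) and Izumo1r, the folate receptor 4 gene, at 75.8 CPM (at least 126-fold). Fabp5, a fatty acid carrier, had 921 against 65.3 CPM, and Dtx1, a Notch target, 283 against 27.9 CPM. Ptcra was higher, 598 against 147 CPM, as were Zap70, the kinase behind the T-cell receptor (log2 ratio 1.69), and Lef1 (1.38). Cpa3 had 24.2 against 482 CPM, Ly6a, also called Sca-1, 26.9 against 255 CPM, and the immediate-early genes Fos and Jun had log2 ratios of -2.62 and -2.30.

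The T-lineage list, with 5 of 25 genes at least 2-fold higher and 0 lower, had a median of 0.19 and the ILC list of -0.18, and neither stood apart from random lists. Cell-cycle genes were higher: 9 of 24 G2 and M phase genes by 2-fold (median 0.80), with Cenpf at 1.89, and 4 of 21 S phase genes (median 0.58), with Rrm2 at 1.19. The early progenitor median was -1.12 over 8 measured genes, among them Hhex at -1.49 and Kit at -1.24, and the dissociation stress median was -0.62. Medians were -0.88 for NK and cytotoxic, -1.13 for myeloid, -0.71 for dendritic and -1.20 for erythroid and mast genes, 0.57 for sort and housekeeping and 0.28 for Myc and ribosome biogenesis genes. With cells weighted equally the erythroid and mast median was 0.40. The named genes were Pdlim4, Cd2, Fabp5, H2-Q2, Gpr83, Izumo1r, Agfg1, Necab1, Dtx1 and Fbp1 among the higher, and Cpa3, Ctla2a, Ly6a, Oasl2, Pbld1, Tcf7, Fos, Zfp36l2, Ralgapa2 and Serpinb1a among the lower, with 65.7% of the WT Pbld1 counts in 1 cell. The Tcf7-/- libraries also differ in sex from all others: Ddx3y, on the Y chromosome, had 381 counts in this library and 0 or 1 in the other DN2-3 libraries, and Xist 1 count against 2414 in WT DN2-3.

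The library labelled Vav-cre DN2-3 held part of the same pattern. Pdlim4 had 333 CPM (at least 553-fold higher than WT), Gpr83 234 CPM (at least 389-fold), Izumo1r 214 CPM (at least 355-fold) and Cd2 189 CPM (at least 313-fold), each against 0 counts. Dtx1 had a log2 ratio of 2.97, Zap70 of 1.77 and the Src family kinase gene Fyn of 1.66. Id2 had 377 against 75 CPM, and Gzma, a granzyme, 9343 against 1078 CPM. Bcl11b, a factor of T-cell commitment, was lower at 263 against 833 CPM, as was Ccr9, a thymic homing receptor, at 32 against 341 CPM.

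Of 25 T-lineage genes here, 3 were at least 2-fold higher and 3 lower (median 0.03), which did not stand apart, while the ILC median of 0.35 over 13 genes and the G2 and M phase median of 0.20 did. The early progenitor median was -0.92, with Lyl1 at 1.82 on 117 against 2 counts. The erythroid and mast median was 2.40, with Hba-a1 at 3.51 and Hbb-bs at 3.34, but 1 cell held 50.8% and 65.7% of these counts. Without cells that carry markers of other blood cell types the erythroid and mast median was -0.45 and the G2 and M phase median -0.43. The haemoglobin genes are themselves such markers, so the fall of the erythroid and mast median follows partly from the choice. The named genes were Pdlim4, Bex1, Gpr83, Izumo1r, Cd2, Adam19, Rdh10, Cers4, Art2b and Ptpn14 among the higher and Sipa1l1, Lyz2, Churc1, Ccr9, Cpa3, Eci1, Ctla2a, Serpinb1a, Glrx5 and Nme4 among the lower. Pdlim4, Cd2, Gpr83 and Izumo1r were named among the higher and Cpa3, Ctla2a and Serpinb1a among the lower genes in both Tcf7-/- and Vav-cre DN2-3.

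Because both comparisons use the same WT library, the genes named in Tcf7-/- DN2-3 were also read in Vav-cre DN2-3 against each Lck-cre plate, libraries that take no part in the first comparison. Of the 10 higher genes, 10 were higher against plate 2 and 9 against plate 1, 9 and 8 of them at least 2-fold, with median log2 ratios of 2.93 and 3.21, each above all of the 10000 random draws of genes of like expression. Of all genes at 50 CPM, 42.8% and 44.6% were higher and 4.15% and 4.18% at least 2-fold. The lower genes were less shared: of the 9 other than Tcf7, 6 were lower against either plate, 5 and 4 at least 2-fold, with medians of -1.35 and -0.58, where 57.2% and 55.4% of all genes were lower and 5.52% and 5.03% at least 2-fold. Ly6a, Oasl2 and Fos were at least 2-fold higher against both plates. H2-Q2 was at 123 CPM in Tcf7-/- and 2.28 CPM in Vav-cre DN2-3, so its level was not shared.

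**Figure D4:**
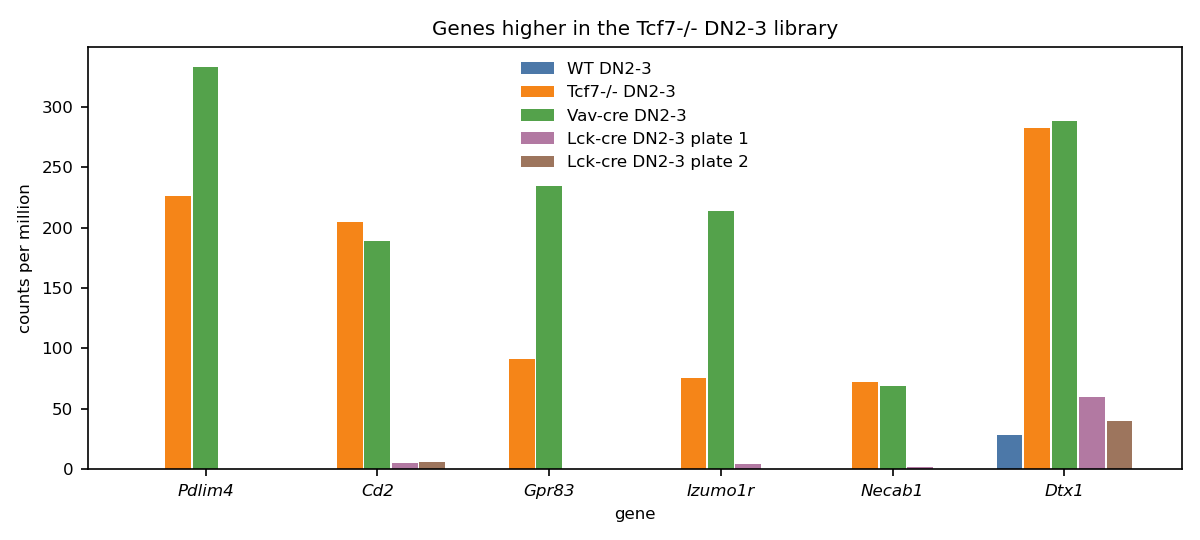
CPM (vertical, starting at 0) of 6 genes named higher in Tcf7-/- DN2-3, in the 5 DN2-3 libraries shown by colour. Pdlim4, Cd2, Gpr83 and Izumo1r lie between 75.8 and 333 CPM in Tcf7-/- and Vav-cre and at 5.65 CPM or less in WT and both Lck-cre plates.

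Lck-cre is active later, in cells already on the T-cell path. The plates labelled Lck-cre DN2-3 had median absolute log2 ratios to WT of 0.32 and 0.31 (0.29 for their mean, which averages out noise), against 0.43 for Tcf7-/- and 0.40 for Vav-cre. Among the lower genes, Acadl, a mitochondrial fatty acid dehydrogenase, had 11.6 against 167 CPM (log2 ratios of -2.70 and -3.47 by plate), and the immediate-early gene Fos 32.7 against 141 CPM. Id2 had a log2 ratio of -1.46 (-1.51 and -1.41) and Ly6a of -1.75. Fabp5 was higher, 195 against 65.3 CPM, and Cd59a, a complement regulator, 69.2 against 12.9 CPM, as was Ptcra (0.97, by plate 1.19 and 0.75).

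Of 10 measured ILC genes 0 were at least 2-fold higher and 2 lower (median -0.71, by plate -0.66 and -0.85). The T-lineage median was -0.18 (-0.15 and -0.11), with 0 of 24 genes 2-fold higher or lower and Ets1 at -0.68, and it stood just apart from random lists, at percentile 2.23. The S phase median was 0.48, with Mcm5 at 0.94, while the plates themselves differed by -0.34. The G2 and M phase median of -0.28, with Mki67 at -1.04, did not stand apart. Medians of -0.49 for dissociation stress, with Jun at -1.46, -0.44 for T-cell leukaemia factors, -0.78 (-1.15 with the bound) for erythroid and mast and 0.20 for Myc and ribosome biogenesis genes did. The named genes were Cd59a, Hmgb3, Fabp5, Oard1, Tmem199, Pigs, Cyb5r3, Gtf2h2 and Capg among the higher and Acadl, Ralgapa2, Ifit1, Fos, Tulp4, Gas5, Elf4, Ly6a, Tbc1d23 and Cryzl1 among the lower. The plates differed for Gas5, at -0.74 and -2.90, and 1 cell held 51.5% of the WT Ifit1 counts. With thinned cells the T-lineage median was 0.04.

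Set directly against Vav-cre, the Lck-cre DN2-3 libraries held far less of the genes that Vav-cre shares with Tcf7-/-. Pdlim4 had 0.171 against 333 CPM on 2 counts (ratio 5.02e-04, interval 6.08e-05 to 1.82e-03), Gpr83 0 counts on both plates against 234 CPM, and Cd2 5.28 against 189 CPM. Id2 had a log2 ratio of -3.65, Gzma of -3.55 and Dtx1 of -2.34. The ILC median was -0.96, with 5 of 11 genes at least 2-fold lower, the early progenitor median 1.08, with Egfl7 at 33 CPM against 0 counts, the NK and cytotoxic median -0.91 (-2.14 with the bound), and the erythroid and mast median -3.28 (-3.83). Medians were 0.61 for S phase, -0.38 for G2 and M phase and -0.10 for T-lineage genes, the last of which did not stand apart. Named genes were Smim3, Churc1, Nme4, Laptm4b, Lyz2, Slc5a9, Tifa, Ctla2a, Use1 and Serpinb1a among the higher and Bex1, Pdlim4, Gpr83, Ifitm3, Izumo1r, Hbb-bs, Adam19, Hba-a2, Hba-a1 and Cd160 among the lower. With the list minimum at 50 CPM the early progenitor median was -1.31 and the NK and cytotoxic median 0.37. Without cells carrying markers of other blood cell types Hba-a1, itself such a marker, had 6.91 against 5.34 CPM.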

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

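The tests of cell makeup, class shares, depth, sex, sorted DN1 cells and timing were chosen after the results were seen, while those of carried-over RNA, of expression by an early T-cell class and of background counts were set before their values were known. The difference between gates in the values that follow was not tested, since each is 1 library against 1.

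Gene lists went opposite ways in the gates for the same genotype. Members were counted as measured per comparison, so the medians of the gates need not cover the same genes. The DN1 medians are also read against a WT library with 1 early progenitor-like cell of 86. In the Tcf7-/- libraries the early progenitor median was 1.60 in DN1 and -1.12 in DN2-3, the myeloid median 0.70 and -1.13, and the erythroid and mast median 1.04, with 3 genes higher and 3 lower of 6, and -1.20. With no list minimum the DN2-3 myeloid median was 0.017, and with cells weighted equally the DN2-3 erythroid and mast median was 0.40. In the Vav-cre libraries the early progenitor median was 1.53 in DN1 and -0.92 in DN2-3. Y-linked genes, which no comparison uses, were counted in the Tcf7-/- libraries. In DN1 they were Ddx3y with 391, Eif2s3y with 732 and Kdm5d with 139 and Uty with 66 counts. In DN2-3 they were Ddx3y with 381, Eif2s3y with 552, Kdm5d with 118 and Uty with 207 counts. The other libraries had at most 1 count of Ddx3y, 7 of Eif2s3y, 4 of Kdm5d and 21 of Uty, so genotype and sex cannot be told apart for germline Tcf7-/-. Xist, the transcript of the inactive X chromosome, was counted in 48 of the 96 Tcf7-/- DN1 cells, never above 5 counts in a cell, beside 1 count in all of Tcf7-/- DN2-3.

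Low counts of DN2-3 genes across the Tcf7-/- DN1 library form the first pattern. Greater depth is argued against, since its median cell held 0.557 times the counts of the WT DN1 cell. Of the 5 genes (Ptcra, Endou, Slc5a9, Pdlim4 and Myl10) at 200 CPM or more in Tcf7-/- DN2-3 and at 2 CPM or less in WT DN1, 100% had a count in at least 10% of its NK-like cells, and the median share of cells was 43.5% in NK-like, 50% in ILC-like and 41.2% in early progenitor-like cells. Expression by an early T-cell class predicts a higher share in progenitor-like than in NK-like cells, and the median ratio of the shares was 0.955 (0.902 to 1.35 over the 5 genes). RNA carried over from DN2-3 cells, including Xist-bearing ones, may therefore account for these low counts, though its source was not traced, and 5 genes are few.

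The lower T-lineage median in both DN1 libraries is the second pattern. Background counts in the WT library are argued against as its cause: with counts of 1 to 5 set to 0 the median was -0.75 in Tcf7-/- and -0.72 in Vav-cre DN1. Background in the Tcf7-/- DN1 library itself, such as its low counts of DN2-3 genes, would raise its T-lineage values. This setting could not have shown such background as the cause. In Vav-cre DN1 a shift between the NK-like and ILC-like classes alone is argued against, since within 39 ILC-like cells against 7 of WT the median was -1.27 (-1.85 to -0.54 resampled, -1.35 to -1.16 with any 1 WT cell left out), with 12 genes lower and 1 higher of 21, beside -0.64 (-1.47 to 0.01) within 9 NK-like cells. The resampled intervals here cover the cells of 1 library against 1 and hold no spread between mice or libraries. A change in cell makeup, with fewer NK-like cells, could account for the lower T-lineage median in Tcf7-/- DN1. There the median within NK-like cells was 0.093 (-0.27 to 0.27 over 1000 resamplings of the cells), but 3 of 24 genes stayed at least 2-fold lower and 4 were higher. Within 30 ILC-like cells the median was -0.27 (-0.67 to 0.29). With the shallow cluster counted as NK-like (47 against 76 cells) it was 0.071 (-0.19 to 0.27). That cluster had 3 of 14 NK markers raised, and its identity is not settled. Makeup, of cell types within the classes in Vav-cre DN1, and a change within cells cannot be told apart. The 9 NK-like and 7 ILC-like cells are few, and in Tcf7-/- DN1 the genes go both ways. The NK-like name does not exclude T cells, so T-lineage values within it may come from a mix of cells. Markers of other types also differ within the ILC-like cells. The NK and cytotoxic, myeloid and dendritic medians there were -1.43, 1.82 and 1.75 in Vav-cre, and -0.85, 1.75 and 1.35 in Tcf7-/- DN1. Their percentiles among random lists were 0, 100 and 99.94 in Vav-cre, and 0, 99.59 and 99.39 in Tcf7-/- DN1. With 7 WT cells, random lists can themselves lie well above 0: a thymic stroma median of 1.02 in Tcf7-/- DN1 was at percentile 63.4. The size of a median alone therefore overstates the difference.

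The third pattern is the set of Pdlim4, Cd2, Gpr83 and Izumo1r, high in Tcf7-/- and Vav-cre and near 0 in WT and Lck-cre DN2-3. In Vav-cre DN2-3 sex is argued against, since it and Lck-cre plate 2 both carry Xist and at most 8 counts of any Y-linked gene, and their median log2 ratio was 4.55 for the 4 genes and 2.93 for the 10 genes named from Tcf7-/- and WT alone. DN1 cells among the sorted cells are argued against too: Cd2 stood at 42.1% of its WT DN1 level in Vav-cre and 45.7% in Tcf7-/- DN2-3, while the median of the abundant genes Cd7, Cd52, Klrd1 and Ccl5 was at most 0.749%. These shares speak to Cd2 and to cells like those of WT DN1 only. All 4 genes were also higher than in DN1 of the same genotype. Pdlim4 had 333 against 24.6 CPM in Vav-cre and 226 against 5.29 CPM in Tcf7-/-. Cd2 had 189 against 142 CPM and 205 against 184 CPM. A single cell type of the DN1 gate was not tested. If the labels hold, earlier deletion of Tcf7 than with Lck-cre is a candidate explanation. The highest value of the 4 genes in WT and Lck-cre was 5.65 CPM, but low levels there are part of how the pattern is defined, so they do not test timing. Earlier deletion cannot be told apart from a difference between single libraries or mice, because Tcf7-/- and Vav-cre have 1 DN2-3 library each. In Tcf7-/- DN2-3, where the median against WT was 3.88, it cannot be told apart from sex either, because the Y-linked counts go with Tcf7-/-.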

How the results depend on the processing

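Results were recomputed under each other choice, and those with counts of 1 to 5 set to 0, without the highest cell, in NK-like cells, with cluster names free of the depth limit or with the totals behind the authors' values were chosen after the results were seen. Given here, in log2 units unless a percent is shown, are values that turned sign, and main values that moved by more than the difference between Lck-cre plates for lists, by more than their 95% interval for genes and shares of cells, or by more than 1.5 times. Of 69 list medians that stood apart, 54 kept their direction under every choice set before the data were examined, and 39 also under the choices added later. Of 229 gene ratios of at least 2-fold, 226 and 224 did wherever they were measured, but 20 and 42 were under 10 CPM in both libraries once cells were left out by type and have no value there. Among the choices set before the data were examined, most turns came without cells carrying markers of other types, which leaves 9 WT, 35 Tcf7-/- and 14 Vav-cre DN1 cells: under the other choices set then, 64 list medians and 228 gene ratios kept their direction. Among the choices added later, NK-like cells alone turned 1 main and 9 other values, and these cells with counts of 1 to 5 set to 0 turned 1 main and 7 other values. Keeping all deposited cells or using the totals behind the authors' values moved 0 of the 18 main results. TMM scaling shifted the median log2 ratio of all genes from -0.11 to 0.11 in Tcf7-/- DN2-3, 0.14 to -0.042 in Vav-cre DN1, -0.097 to 0.060 in Vav-cre DN2-3, -0.052 to 0.051 in Lck-cre and 0.19 to 0.016 in the WT gates. For the values below the cause was not tested, except that a scaling factor shifts all genes of a comparison alike.

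With cells of at least 2000 genes, the T-lineage median was -0.90 (Vav-cre DN1) and the ILC median was 0.62 (Vav-cre DN1). Tcf7 was 0.61 (Vav-cre DN1).

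With cells weighted equally, the T-lineage median was 0.87 (the WT gates), -0.38 (Tcf7-/- DN1), -0.84 (Vav-cre DN1) and -0.12 (Vav-cre DN2-3) and the ILC median was 0.99 (Tcf7-/- DN1), 1.43 (Vav-cre DN1), -0.46 (Tcf7-/- DN2-3) and -0.56 (Lck-cre). Tcf7 was 0.56 (Tcf7-/- DN1), 1.85 (Vav-cre DN1) and 0.098 (Vav-cre DN2-3) and the erythroid and mast median was 0.40 (Tcf7-/- DN2-3). The G2 and M phase median was 0.0040 (Lck-cre).

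With a pseudocount of 1 CPM, the ILC median was 1.15 (Tcf7-/- DN1), 1.52 (Vav-cre DN1), -0.35 (Tcf7-/- DN2-3) and -0.99 (Lck-cre).

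With TMM factors, the T-lineage median was 0.41 (the WT gates), -0.76 (Tcf7-/- DN1), -0.84 (Vav-cre DN1), 0.42 (Tcf7-/- DN2-3), 0.20 (Vav-cre DN2-3) and -0.079 (Lck-cre) and the ILC median was 1.15 (Vav-cre DN1), -0.068 (Tcf7-/- DN2-3) and 0.51 (Vav-cre DN2-3). Tcf7 was 1.20 (Vav-cre DN1), -2.49 (Tcf7-/- DN2-3) and 0.33 (Vav-cre DN2-3).

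With DESeq2 size factors, the T-lineage median was 0.39 (the WT gates), -0.77 (Tcf7-/- DN1), -0.77 (Vav-cre DN1), 0.39 (Tcf7-/- DN2-3), 0.23 (Vav-cre DN2-3) and -0.091 (Lck-cre) and the ILC median was 1.21 (Vav-cre DN1), -0.084 (Tcf7-/- DN2-3) and 0.54 (Vav-cre DN2-3). Tcf7 was -2.52 (Tcf7-/- DN2-3) and 0.36 (Vav-cre DN2-3).

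On the mean deposited log2 values, the T-lineage median was 0.83 (the WT gates), -0.085 (Tcf7-/- DN1), -1.38 (Vav-cre DN1), 0.48 (Tcf7-/- DN2-3), -0.047 (Vav-cre DN2-3) and -0.097 (Lck-cre) and the ILC median was 0.52 (Tcf7-/- DN1), 0.67 (Vav-cre DN1), 0.097 (Tcf7-/- DN2-3), 0.098 (Vav-cre DN2-3) and -0.16 (Lck-cre). Tcf7 was 0.98 (Tcf7-/- DN1), 1.17 (Vav-cre DN1), -3.52 (Tcf7-/- DN2-3), 0.048 (Vav-cre DN2-3) and -0.67 (Lck-cre) and the G2 and M phase median was 0.034 (Lck-cre). Il2ra was -0.55 (Vav-cre against Tcf7-/- DN1).

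With thinned cells, the T-lineage median was 0.88 (the WT gates), -0.27 (Tcf7-/- DN1), -0.78 (Vav-cre DN1) and 0.042 (Lck-cre) and the ILC median was 1.09 (Tcf7-/- DN1), -0.49 (Tcf7-/- DN2-3) and 0.19 (Vav-cre DN2-3). Tcf7 was 0.28 (Tcf7-/- DN1), 1.90 (Vav-cre DN1) and -2.85 (Tcf7-/- DN2-3) and the G2 and M phase median was -0.098 (Lck-cre). The share of cells with Tcf7 counts was 37.3% (WT DN1), 51.3% (Tcf7-/- DN1), 48.9% (Tcf7-/- DN2-3) and 89.7% (Lck-cre DN2-3 plate 1).

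Without cells carrying markers of other types, the early progenitor median was 0.63 (the WT gates) and the T-lineage median was -0.26 (Tcf7-/- DN1) and -0.13 (Vav-cre DN2-3). The ILC median was 0.98 (Tcf7-/- DN1) and Tcf7 was -0.89 (Tcf7-/- DN1), 0.41 (Vav-cre DN1) and -2.93 (Tcf7-/- DN2-3). The erythroid and mast median was -0.45 (Vav-cre DN2-3) and the G2 and M phase median was -0.43 (Vav-cre DN2-3). Hba-a1 was -0.71 (Vav-cre DN2-3) and Hbb-bs was -0.19 (Vav-cre DN2-3). The myeloid median was -0.13 (Vav-cre against Tcf7-/- DN1) and the dendritic median was -0.32 (Vav-cre against Tcf7-/- DN1). The Myc and ribosome biogenesis median was 0.21 (Vav-cre against Tcf7-/- DN1). The falls of the dendritic, myeloid and erythroid and mast medians and of the haemoglobin genes follow partly from the choice, because these genes set which cells were left out.

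With counts of 1 to 5 set to 0, the T-lineage median was -0.75 (Tcf7-/- DN1) and -0.72 (Vav-cre DN1) and the DN3 and DP stage median was -0.22 (Tcf7-/- DN1). Tcf7 was -0.82 (Tcf7-/- DN1) and the ILC median was 1.20 (Vav-cre DN1) and -0.32 (Tcf7-/- DN2-3). The share of cells with Tcf7 counts was 32.6% (WT DN1), 20.8% (Tcf7-/- DN1), 37.9% (Vav-cre DN1), 88.6% (WT DN2-3), 45.2% (Tcf7-/- DN2-3), 81.6% (Vav-cre DN2-3), 83.5% (Lck-cre DN2-3 plate 1) and 77% (Lck-cre DN2-3 plate 2).

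Without the highest cell of each gene, the T-lineage median was 0.68 (the WT gates), -0.87 (Vav-cre DN1) and -0.055 (Vav-cre DN2-3) and the ILC median was 0.93 (Tcf7-/- DN1), 0.14 (Tcf7-/- DN2-3) and 0.23 (Vav-cre DN2-3). Ccr7 was -0.12 (Vav-cre against Tcf7-/- DN1).

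In NK-like cells alone, the T-lineage median was 0.093 (Tcf7-/- DN1) and the ILC median was 0.50 (Tcf7-/- DN1) and 0.085 (Vav-cre DN1). The NK and cytotoxic median was 0.54 (Tcf7-/- DN1) and 0.36 (Vav-cre DN1) and the myeloid median was -0.052 (Tcf7-/- DN1). The erythroid and mast median was -0.30 (Tcf7-/- DN1) and Tcf7 was -0.23 (Tcf7-/- DN1) and 0.35 (Vav-cre DN1). Cd163l1 was -0.55 (Tcf7-/- DN1) and the gamma-delta T median was -0.16 (Vav-cre DN1). The dendritic median was -0.81 (Vav-cre DN1) and -0.55 (Vav-cre against Tcf7-/- DN1) and the T-cell leukaemia factor median was -0.027 (Vav-cre DN1). Over the members at 10 CPM or more within these cells, 3 of these medians kept their sign: myeloid 0.23 (Tcf7-/- DN1, 5 members), gamma-delta T 1.37 (Vav-cre DN1, 5) and T-cell leukaemia factor 0.15 (Vav-cre DN1, 10).

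In NK-like cells with counts of 1 to 5 set to 0, the T-lineage median was 0.072 (Tcf7-/- DN1) and -0.58 (Vav-cre DN1) and the ILC median was 0.46 (Tcf7-/- DN1) and 0 (Vav-cre DN1). The NK and cytotoxic median was 0.59 (Tcf7-/- DN1) and 0.43 (Vav-cre DN1) and the erythroid and mast median was -0.79 (Tcf7-/- DN1). Tcf7 was -0.78 (Tcf7-/- DN1) and 0.28 (Vav-cre DN1) and Cd163l1 was -1.49 (Tcf7-/- DN1). The dendritic median was -1.13 (Vav-cre DN1) and -0.83 (Vav-cre against Tcf7-/- DN1) and the Myc and ribosome biogenesis median was 0.20 (Vav-cre against Tcf7-/- DN1).

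With no list minimum, the T-lineage median was -0.60 (Tcf7-/- DN1) and the ILC median was 0.65 (Tcf7-/- DN1), 0.96 (Vav-cre DN1), -0.065 (Tcf7-/- DN2-3), 0.063 (Vav-cre DN2-3) and -0.40 (Lck-cre). The myeloid median was 0.017 (Tcf7-/- DN2-3).

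With a list minimum of 50 CPM, the T-lineage median was -0.76 (Tcf7-/- DN1) and 0.11 (Tcf7-/- DN2-3) and the ILC median was 1.14 (Tcf7-/- DN1), -0.41 (Tcf7-/- DN2-3) and -0.39 (Lck-cre). The early progenitor median was -1.31 (Lck-cre against Vav-cre) and the NK and cytotoxic median was 0.37 (Lck-cre against Vav-cre).

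With a single Lck-cre plate left out, the T-lineage median lay between -0.15 and -0.11 and the ILC median between -0.85 and -0.66. At Leiden resolution 2 the ILC-like share was 6.25% (Tcf7-/- DN1) and 1.72% (Vav-cre DN1), and at resolution 0.5 the early progenitor-like share was 42.7% (Tcf7-/- DN1). With cluster names free of the depth limit the NK-like share was 49% (Tcf7-/- DN1).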

Other observations

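These clusters were described only after they were seen. Vav-cre and part of the Tcf7-/- DN2-3 cells clustered apart, while WT and Lck-cre cells shared clusters in unlike proportions. A cluster with 28 of 88 WT cells held 44 of 91 and 30 of 87 Lck-cre cells by plate. Another held 44 WT cells and 12 and 22 Lck-cre cells, and a further cluster 7 and 21 and 24. In Vav-cre DN2-3, 68 of 76 cells (89.5%, interval 80.3% to 95.3%) fell in a cluster that held 2 cells of Tcf7-/- DN2-3 and 0 of WT and Lck-cre DN2-3, with Ly6c1, Bex1, the haemoglobin genes Hbb-bs, Hba-a2 and Hba-a1, Gpr83, Rdh10 and Gzma among its leading genes. In Tcf7-/- DN2-3, 35 of 93 cells (37.6%, 27.8% to 48.3%) fell in the cluster named DN2-DN3 T progenitor-like, with Il2ra, Ptcra, Rag1, Rag2, Dtx1 and Lef1 raised, against 1 of 88 WT cells, 0 of 76 Vav-cre cells and 2 of 87 cells of Lck-cre plate 2. That contrast depends on the clustering: clusters of this name held 33 of 93 Tcf7-/- and 31 of 88 WT cells with 1000 variable genes, 42 and 29 at Leiden resolution 2 and 0 of both at 0.5. Markers are compared with the other cells, mostly of the same gate, and 98.9% of WT DN2-3 cells stayed unnamed. The clusters with 28 and 44 of the 88 WT cells had 5 and 4 DN2-DN3 T progenitor-like markers raised. They stayed unnamed because their 10 leading genes held 0 markers of that class and 1 of another. A cluster of deep cells led by the cell-cycle genes Pbk, Rrm2, Birc5 and Top2a took 59.7% of its 72 cells from Tcf7-/- DN2-3. A cluster of 5 DN1 cells had all 10 measured B-like markers raised, among them Cd79a and Ms4a1, and stayed unnamed because its leading genes held more dendritic markers such as Cd74 and H2-Aa.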
